A study of Mus musculus with 8 samples.

How the data were processed

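RNA was measured in 8 libraries of flow-sorted mouse lung cells, 4 of CD249+ and 4 of CD249− fibroblasts, from 4 wild-type C57BL/6J mice numbered 2, 7, 8 and 10 in the labels. Per the labels, cells of digested lungs that lacked CD45, CD326 and CD31 were divided by surface CD249, with equal cell numbers taken for both fractions of a lung. The count columns are named Ctrl and LIF with the mouse number, abbreviations that the labels do not explain. The sample descriptions carry the same names, and the titles of those samples give Ctrl as CD249− and LIF as CD249+. Total RNA was reverse transcribed from oligo(dT) and amplified with the SMART-Seq V4 kit from an input of 10 ng, made into libraries with Nextera XT and sequenced as single reads of 75 bp on an Illumina NextSeq, per the labels' protocols. This kind of library does not mark strand, so reads of overlapping and antisense genes cannot be told apart, and amplified reads without molecular identifiers are not independent molecules.

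The deposited table holds estimated counts per gene (expected counts that need not be whole) for 25509 mouse Ensembl genes and 92 ERCC spike-in entries. The spike-in entries are 0 in every library and were left out. Of the gene values, 12.0% are not whole, and library totals differ, from 23011383 to 31906414. The submitters' processing notes name bcl2fastq 2.20, STAR 2.6.1, RSEM 1.2.28, DESeq2 1.26.0 and R 3.6.3 without saying which step each served. They also name the genome build GRCh38, a human build, while the identifiers in the table are mouse genes, so the build behind the counts is not given in the sources used here. Where estimated counts divide shared reads among similar genes, values of close paralogs such as the haemoglobin, Ly6 and H2 genes are uncertain. Gene coordinates were taken from GENCODE M21 on GRCm38 by Ensembl identifier. In that annotation 99.0% of the identifiers were found when the version suffix was ignored, and 68.0% with the same version.

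Estimated counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with the sorted fraction as the group, which left 14524 of the 18572 genes with any count. Libraries were scaled by TMM, and CD249+ was compared with CD249− by edgeR 4.0.16's quasi-likelihood F test in R 4.3.3, two-sided, with group as the only term and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. Fold changes are log2 of CD249+ over CD249−, standard errors come from the same fit, and CPM, the counts relative to the library total, use totals scaled by TMM. The processing notes name no block, so the group-only fit was the main one and the fit with mouse as a block was an alternative. Both fractions came from the same lung, and deviations from the group mean correlated at 0.132 to 0.285 between libraries of the same mouse, against -0.212 to 0.0515 between libraries of different mice (across genes, which are not independent replicates). The mouse numbers were therefore taken to pair the libraries.

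Genes to be named were chosen by a rule written before the data were examined: Enpep, the 10 largest increases and the 10 largest decreases among called genes with a mean of at least 10 CPM in the higher group, the same direction in all 4 mice and a symbol that is not a predicted or clone name, up to 4 members with the smallest p of each list described, and the gate genes Ptprc, Epcam and Pecam1. A few genes that the rule selects are not reported here. Other list members are named as exceptions or where a list had few calls, and these were chosen after their values were seen and are not among the genes followed through the alternative settings. The main design, the alternative settings and 36 gene lists were also written before the data were examined. The lists cover cell types (alveolar and adventitial fibroblasts, ductal and peribronchial myofibroblasts, smooth muscle, pericytes, mesothelium, endothelium, epithelium, leukocytes, red cells and platelets, nerve and Schwann cells, chondrocytes), functions (lipid droplets and uptake, fatty acid oxidation, cholesterol synthesis, retinoid metabolism, fibrillar collagens, basement membrane, elastic fibre, matrix proteases, the renin-angiotensin system, Wnt, BMP and TGF-beta, FGF and PDGF, hedgehog, lung mesenchyme transcription factors, chemokines and cytokines, complement, interferon and antigen presentation, glutathione and xenobiotic metabolism, hypoxia and glycolysis) and RNA quality or state (immediate early and dissociation genes, cell cycle, oxidative phosphorylation, ribosomal proteins, genes of the mitochondrial genome). Enpep is in none of them. Lists share members, so their tests are not independent. Each list was tested with camera of limma 3.58.1, two-sided, at a preset inter-gene correlation of 0.01, with adjustment over the lists, and again with a correlation estimated from the 8 libraries. Library measures and list means were compared by two-sided exact permutation tests, for which the smallest p that 4 against 4 can give is 0.0286. Except where called paired, these tests ignore the pairing by mouse. A permutation within the 4 pairs can give no p under 0.125.

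Alternatives were other scalings (RLE, upper quartile, library size only), no low-count filter or at least 1 CPM in 4 libraries, robust dispersion, unrounded values, the block on mouse, DESeq2 1.42.0 with and without the block, limma-voom, an adjusted p under 0.01, a test against a log2 fold change of 0.5, fry, list members of at least 10 CPM, and leaving out each library and each mouse. Fits on mice 7 and 8 alone and on mice 2 and 10 alone were added after seeing the data. The steps were tested on simulated counts of 14524 genes at the depth and spread of this comparison: of 100 genes changed 2-fold, 66% were called, and of 100 changed 4-fold, 89%, with 6 false calls. The changed genes were drawn from those with a CD249− mean of at least 1 CPM. Far fewer genes were changed than were called in the data, and genes were simulated independently, so these shares are not the power of this comparison. Counts of libraries of the same group differed by 39.3 to 140 times the chi-square of sampling noise per degree of freedom, so no library held the same amplified material sequenced again, while a second amplification of the same RNA is not excluded by this measure. The counting error of a single gene is small at these depths except near the floor, and the 4 mice per group limit the precision of the comparison.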

Results

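Lung cells of 4 mice that carried none of the leukocyte, epithelial and endothelial surface markers CD45, CD326 and CD31 were sorted into a CD249+ and a CD249− fraction, and the RNA of both fractions was sequenced. CD249 is glutamyl aminopeptidase, a cell-surface enzyme encoded by Enpep that trims acidic residues from peptides such as angiotensin II. The comparison asks how lung fibroblasts with CD249 differ in expression from those without it in the same lung. Library totals ran from 23011383 to 31906414 counts and did not differ between the fractions past the threshold (exact permutation p = 0.429), with 15456 to 16526 genes detected per library. The 50 most abundant genes took 13.6% ± 0.309 of CD249− counts and 17.7% ± 2.39 of CD249+ counts (SD, n = 4, exact permutation p = 0.0286). Gsn, which encodes the actin-severing protein gelsolin, was the most abundant gene in every library. Adjusted p values of single genes are from edgeR's quasi-likelihood test and those of gene lists from camera.

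CD249+ cells expressed Enpep and genes of alveolar fibroblasts, ductal myofibroblasts and pericytes at far higher levels than CD249− cells, with collagen, elastic fibre, hedgehog, Wnt and growth factor genes. CD249− cells expressed endothelial, antigen presentation and some platelet and mesothelial genes at higher levels. Relative to 8 core collagen genes, chosen after the data were seen, the alveolar mean rose by 1.205 log2 CPM (exact permutation p = 0.0286). The pericyte mean rose by 0.2896 log2 CPM relative to them (exact permutation p = 0.429), and the ductal list was not compared with them. With an estimated correlation between genes camera called 0 of 36 lists (lowest adjusted p = 0.274, 5 at an unadjusted p under 0.05), and the list calls given here are at a preset one. Enpep itself (ENSMUSG00000028024.14, chromosome 3, 129269175 to 129332720, minus strand, GRCm38) rose from 8.98 ± 5.62 to 241 ± 64.8 CPM (SD, n = 4), a 26.7-fold difference seen in all 4 mice (log2 fold change 4.74, SE 0.41, adjusted p = 3.11e-05). The single libraries of mice 2, 7, 8 and 10 gave 7.54, 5.99, 5.13 and 17.3 CPM of Enpep in CD249− cells and 240, 221, 175 and 329 CPM in CD249+ cells.

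**Figure D1:**
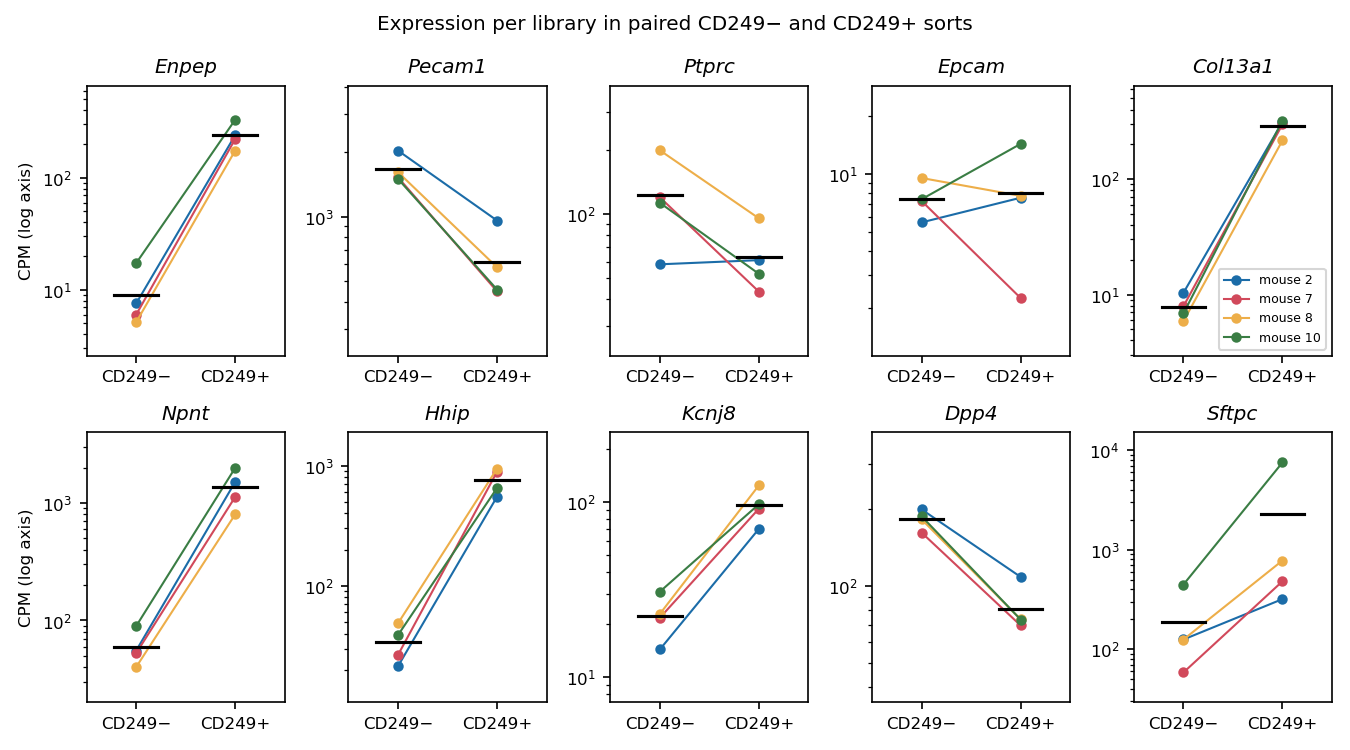
CPM per library (log axis) of 10 genes in the CD249− and CD249+ cells of the 4 mice, with lines joining the libraries of a mouse and black bars at the group means. Enpep, Col13a1, Npnt, Hhip and Kcnj8 lie higher in every CD249+ library than in any CD249− library, Pecam1 and Dpp4 are lower in CD249+ cells of all 4 mice, and Sftpc in CD249+ cells of mouse 10 stands at 7551 CPM.

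Of 14524 genes tested, 4468 changed (30.8%), 2455 of them higher and 2013 lower in CD249+ cells. The direction was the same in all 4 mice for 2431 of the genes that rose and 1989 of those that fell. At least 2-fold differences were found for 1513 genes that rose and 759 that fell, and at least 8-fold differences for 326 and 8. Slc22a3, an organic cation transporter (ENSMUSG00000023828.2, chromosome 17, 12418960 to 12507704, GRCm38), showed the largest increase of the named genes, from 0.203 ± 0.234 to 22.4 ± 7.43 CPM (SD, n = 4, log2 fold change 6.70, SE 0.76, adjusted p = 0.00017). It was followed by the G protein-coupled estrogen receptor gene Gper1 (5.71, SE 0.44), the sulfotransferase gene Chst8 (5.70, SE 0.63) and the transmembrane collagen gene Col13a1 (5.21, SE 0.21). The beta-adrenergic receptor gene Adrb3, the amino acid transporter gene Slc36a2, Amph, the cGMP-dependent kinase gene Prkg2 and the collagen prolyl hydroxylase gene P4ha3 rose by 4.75 to 5.03. In CD249− cells Slc22a3 stood at 0 CPM in mice 2 and 8, and Chst8 and Adrb3 in mouse 8. The sizes and order of their increases therefore rest on values near the floor. Without the CD249− library of mouse 10, Amph gave 5.62 and Prkg2 5.54. Gper1, at 0.505 ± 0.346 CPM in CD249− cells (SD, n = 4), gave 6.44 without both libraries of mouse 2. The largest decreases were those of Bpifa1, a secreted airway protein (log2 fold change -4.94, SE 1.18, adjusted p = 0.0103), and the mesothelial genes Msln (-3.13, SE 0.48), Lrrn4 (-3.10, SE 0.41) and Upk3b (-2.56, SE 0.52), with Cytl1 at -2.56 (SE 0.28). Bpifa1 stood at 46.2 CPM in CD249− cells of mouse 10 and gave -2.76 without that library. The platelet genes Gp1ba, Gp5, Tubb1 and Ppbp and the coagulation factor gene F5 had log2 fold changes of -2.85, -2.74, -2.61, -2.59 and -2.80. Without the CD249− library of mouse 7 these 5 genes gave -2.16, -1.69, -1.77, -1.64 and -2.41, and Gp1ba, Gp5 and F5 were no longer called (adjusted p = 0.0577 to 0.111). At least 1 of those 3 calls was also lost without the CD249− library of mouse 8 or without any single CD249+ library (adjusted p = 0.0518 to 0.0837), and without the CD249+ library of mouse 7 Gp1ba gave -3.52 and Gp5 -3.72.

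The split of calls depended on scaling: with library size only, 2106 genes were higher and 2689 lower. Haemoglobin transcripts were high in both libraries of mice 7 and 8 and low in those of mice 2 and 10, and the fits within these pairs of mice gave 3028 calls (1777 higher, 1251 lower) and 668 calls (570 higher, 98 lower), while leaving out mouse 8 gave 2978, and the calls of lower genes fell to 1341, 1201 and 1291 without mouse 7, 8 or 10.

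The alveolar fibroblast list, markers of the lipid-bearing fibroblasts of the alveolar wall, moved furthest. Of its 23 measured members 20 rose, 1 fell and 2 did not pass, with the same counts adjusted over the list alone, and the median log2 fold change was 3.39 (camera adjusted p = 5.09e-14, and adjusted p = 0.274 with an estimated correlation). Col13a1 (ENSMUSG00000058806.14, chromosome 10, 61838236 to 61979108, GRCm38) rose from 7.76 ± 1.92 to 287 ± 47.9 CPM (SD, n = 4, adjusted p = 8.98e-07). Nebl rose by 4.36, the matrix protein gene Spon1 by 3.68 and Limch1 by 3.50. The sodium channel gene Scn7a fell by 0.60 (adjusted p = 0.00882). The lipid genes Lpl, at -0.12 (adjusted p = 0.669), and Plin2, at 0.08 (adjusted p = 0.694), did not pass. In the same comparison the endothelial list had a median of -1.46.

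Ductal and peribronchial myofibroblast markers also rose, 13 of 15 measured members over all genes and adjusted over the list alone, with a median of 2.64 (camera adjusted p = 3.83e-08, and adjusted p = 0.274 with an estimated correlation). Hhip, a hedgehog-binding antagonist, went from 33.9 ± 12.3 to 758 ± 188 CPM (SD, n = 4, log2 fold change 4.49, SE 0.30), the nucleotide-sugar receptor gene P2ry14 rose by 3.25 and Enpp2, which encodes autotaxin, by 2.64. Among pericyte markers 17 of 20 measured members rose, 1 fell and 2 did not pass, with the same counts adjusted over the list alone. The median log2 fold change was 2.27 (camera adjusted p = 8.68e-08, and adjusted p = 0.274 with an estimated correlation). The potassium channel genes Kcnk3 and Kcnj8 rose by 3.42 and 2.08, the guanylate cyclase gene Gucy1a3 by 2.80 and Tbx5 by 3.51. The member that fell was Mcam at -1.08 (adjusted p = 0.0038), an adhesion molecule also made by endothelium. Rgs5, at -0.22 (adjusted p = 0.666), and Ebf2, at 0.13 (adjusted p = 0.900), did not pass. Of 15 smooth muscle genes 11 rose and 4 did not pass, and 13 rose adjusted over the list alone, with a median of 1.64 (camera adjusted p = 0.000188, and adjusted p = 0.365 with an estimated correlation). Des, the gene of the intermediate filament desmin, rose by 2.62, Tagln by 1.98 and Synpo2 by 1.92.

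Adventitial fibroblast markers moved both ways: of 28 measured members 11 rose, 4 fell and 13 did not pass, and 12 rose and 4 fell adjusted over the list alone. Pcolce2, an enhancer of procollagen processing, rose by 2.39, the alcohol dehydrogenase gene Adh7 by 3.12 and the dermatopontin gene Dpt by 1.64. Dpp4 fell from 182 ± 15.6 to 81.4 ± 18.0 CPM (SD, n = 4, log2 fold change -1.16, adjusted p = 0.000323), with Ly6c1 (-1.52), Ly6a (-1.49) and Sema3c (-1.10), and Pi16 stood at -0.17 (adjusted p = 0.776). The list had a median of 0.45 and was not called (camera adjusted p = 0.108), but it was with mouse as a block (median 0.38, adjusted p = 0.037) and without the CD249+ library of mouse 2 (median 0.70, adjusted p = 0.00829). With all libraries the list gave adjusted p = 0.701 with an estimated correlation, and 0.687 with the block as well.

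**Figure D2:**
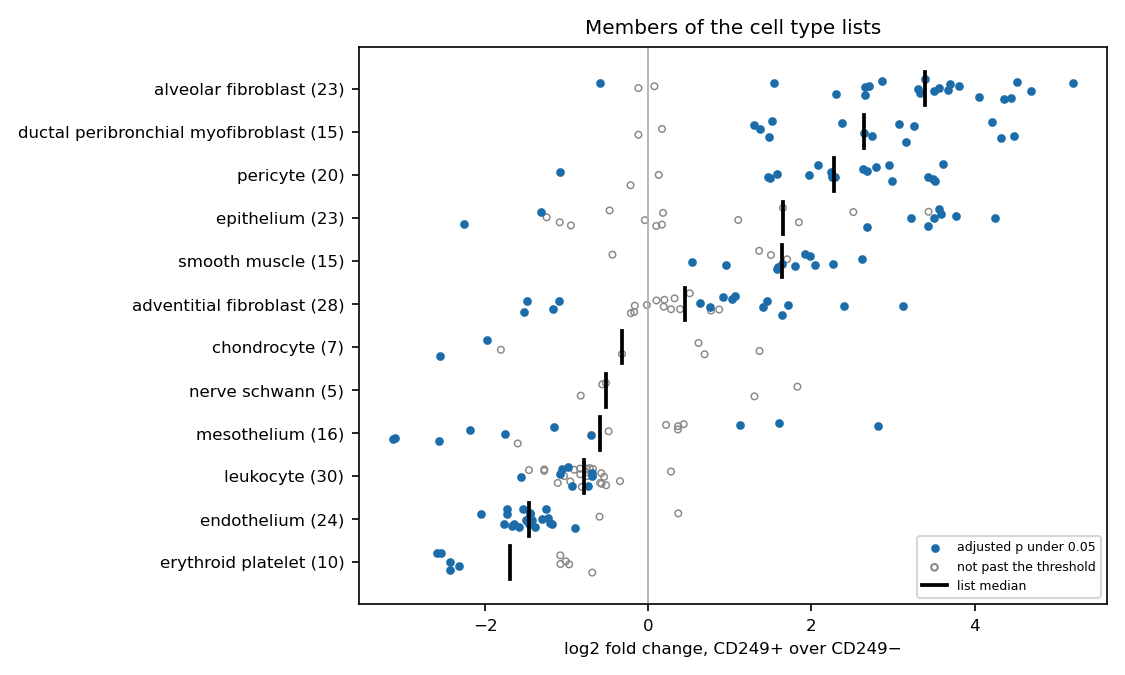
Log2 fold change, CD249+ over CD249−, of each measured member of the 12 cell type lists (number of members in parentheses), with filled points for adjusted p under 0.05, open points for the rest and a bar at the list median. Alveolar fibroblast, ductal myofibroblast and pericyte members lie to the right at medians of 3.39, 2.64 and 2.27, and endothelial members to the left at -1.46.

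Genes of cell types outside the sorted gate were measured in both fractions. Of 24 endothelial genes 22 fell in CD249+ cells and 2 did not pass, with the same counts adjusted over the list alone. The list had a median of -1.46 (camera adjusted p = 8.95e-12, and adjusted p = 0.314 with an estimated correlation). Pecam1, which encodes the gate antigen CD31, stood at 1667 ± 248 CPM in CD249− cells and 611 ± 239 CPM in CD249+ cells (SD, n = 4, log2 fold change -1.45, adjusted p = 0.0017). Plvap, a gene of fenestrated endothelium, ranked 6 among all genes of CD249− cells at 3606 ± 623 CPM and stood at 1272 ± 450 CPM in CD249+ cells (SD, n = 4). The endomucin gene Emcn fell by 1.73, Sox17 by 1.48, Cdh5 by 1.45 and Erg by 1.21. Of 30 leukocyte genes 8 fell and 22 did not pass, and 3 fell adjusted over the list alone. Over its members the median was -0.79 (camera adjusted p = 0.000585, and adjusted p = 0.457 with an estimated correlation). The class II antigen genes H2-Ab1 and H2-Aa fell by 1.08 and 0.98, and the H2-Aa call was lost without both libraries of mouse 7 or of mouse 8 (adjusted p = 0.0561 and 0.0584). Ptprc, the gene of the gate antigen CD45, stood at 123 ± 58.0 and 63.1 ± 22.8 CPM (SD, n = 4, log2 fold change -0.96, adjusted p = 0.0635, and 0.0126 with mouse as a block). Of 10 red cell and platelet genes 5 fell and 5 did not pass, with the same counts adjusted over the list alone, at a median of -1.70 (camera adjusted p = 0.0283, and adjusted p = 0.603 with an estimated correlation). The platelet genes Ppbp, Gp9, Pf4 and Itga2b fell by 2.59, 2.54, 2.44 and 2.43, and without the CD249− library of mouse 7 they gave -1.64, -1.58, -1.62 and -1.57. Without both libraries of mouse 8 the calls of Ppbp and Pf4 were lost (adjusted p = 0.0511 and 0.0551). The list's call was lost with library size only (adjusted p = 0.0706) and without the CD249− library of mouse 8 or the CD249+ library of mouse 2 or 10 (adjusted p = 0.0725, 0.0865 and 0.0768), and with members of at least 10 CPM alone (adjusted p = 0.0541).

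Mesothelial genes moved both ways, 7 of 16 lower, 3 higher and 6 not past the test, with the same counts adjusted over the list alone. The median log2 fold change was -0.59 (camera adjusted p = 0.0846). Msln fell from 38.6 ± 19.3 to 4.40 ± 2.17 CPM and Gpm6a from 18.0 ± 9.27 to 3.94 ± 1.07 CPM, while the uroplakin gene Upk1b rose from 8.87 ± 4.33 to 62.6 ± 16.9 CPM (SD, n = 4). The list was called without the CD249− library of mouse 2 or the CD249+ library of mouse 7 or 8 (adjusted p = 0.0313, 0.0449 and 0.0375), with no low-count filter (median -0.70, adjusted p = 0.0241), and in mice 7 and 8 alone (adjusted p = 0.0329) and mice 2 and 10 alone (adjusted p = 0.0229). With all libraries it gave adjusted p = 0.603 with an estimated correlation. Among 23 epithelial genes 8 rose, 2 fell and 13 did not pass, 9 rose and 2 fell adjusted over the list alone, and the list was not called (median 1.65, camera adjusted p = 0.375). Epcam, the gene of the gate antigen CD326, did not differ past the threshold at 7.46 ± 1.62 and 7.98 ± 4.97 CPM (SD, n = 4, adjusted p = 0.894). The surfactant genes Sftpc, Sftpb and Sftpa1 rose by 3.59, 3.77 and 3.56 (adjusted p = 0.0313, 0.0264 and 0.0297). Sftpc stood at 320, 483, 781 and 7551 CPM in CD249+ cells of mice 2, 7, 8 and 10, and it gave 1.48 without the last of these libraries (adjusted p = 0.112) and 4.47 without the CD249− library of mouse 10. For Sftpb these values were 1.54 and 4.59, and for Sftpa1 1.53 and 4.32. All 3 surfactant calls were lost without any of the CD249− libraries of mice 2, 7 and 8 or the CD249+ library of mouse 10 (adjusted p = 0.0655 to 0.112). Without both libraries of mouse 10 they were kept, at 2.36 for Sftpc, 2.36 for Sftpb and 2.29 for Sftpa1 (adjusted p = 0.00489, 0.00326 and 0.0122), and without both libraries of mouse 7 or of mouse 8 all 3 were lost (adjusted p = 0.0625 to 0.0936). Hopx, a gene of flat alveolar epithelium, fell by 1.31, from 214 ± 17.2 to 86.3 ± 28.5 CPM (SD, n = 4). These levels are far above those of Epcam, and which cells the Hopx transcripts came from was not tested. Of 7 chondrocyte genes Cytl1 (-2.56) and Comp (-1.98) fell and 5 did not pass, also adjusted over the list alone (median -0.32, camera adjusted p = 0.336). None of 5 nerve and Schwann cell genes was called by edgeR or adjusted over the list alone, 1 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0. Their median was -0.52, their mean 0.24, and camera's direction was down (adjusted p = 0.951).

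Matrix genes rose broadly in CD249+ cells, the fraction with the lower endothelial median of -1.46. A higher share of fibroblasts among the CD249+ cells was not tested as an explanation for these rises. Nor was it tested for the signalling, metabolic, complement and chemokine lists below. In the fibrillar collagen list, with its processing enzymes, 20 of 25 measured members rose and 5 did not pass, and 21 rose adjusted over the list alone. The list had a median of 1.35 (camera adjusted p = 6.90e-09, and adjusted p = 0.274 with an estimated correlation). P4ha3 rose by 4.75, Pcolce2 by 2.39, Col16a1 by 2.22 and the lysyl oxidase gene Loxl2 by 1.46. Of 19 elastic fibre entries, which hold Ltbp4 under 2 identifiers, 16 rose, 1 fell and 2 did not pass, with the same counts adjusted over the list alone. Over its members the median was 1.46 (camera adjusted p = 1.53e-07, and adjusted p = 0.314 with an estimated correlation). Ltbp2, a latent TGF-beta binding protein gene, rose by 3.24, Mfap4 by 2.71, Efemp1 by 2.62 and Emilin1 by 1.49, and Mfap2 fell by 0.62. Of 29 basement membrane genes 14 rose, 2 fell and 13 did not pass, 14 rose and 3 fell adjusted over the list alone, and the median was 0.61 (camera adjusted p = 0.00348, and adjusted p = 0.457 with an estimated correlation). Npnt, the integrin ligand nephronectin, went from 59.4 ± 21.2 to 1359 ± 514 CPM (SD, n = 4, log2 fold change 4.51), the laminin genes Lamb1 and Lama4 rose by 2.77 and 2.33, and Lama5 and Hmcn1 fell by 1.17 and 0.71. Of 25 matrix protease and inhibitor genes 17 rose, 1 fell and 7 did not pass, 19 rose and 1 fell adjusted over the list alone, and the median was 1.01 (camera adjusted p = 2.58e-07, and adjusted p = 0.314 with an estimated correlation). Adamts8 rose by 4.32, Adamtsl2 by 2.78, Adamts15 by 2.71 and Mmp11 by 2.38, and Mmp9 fell by 1.10.

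**Figure D3:**
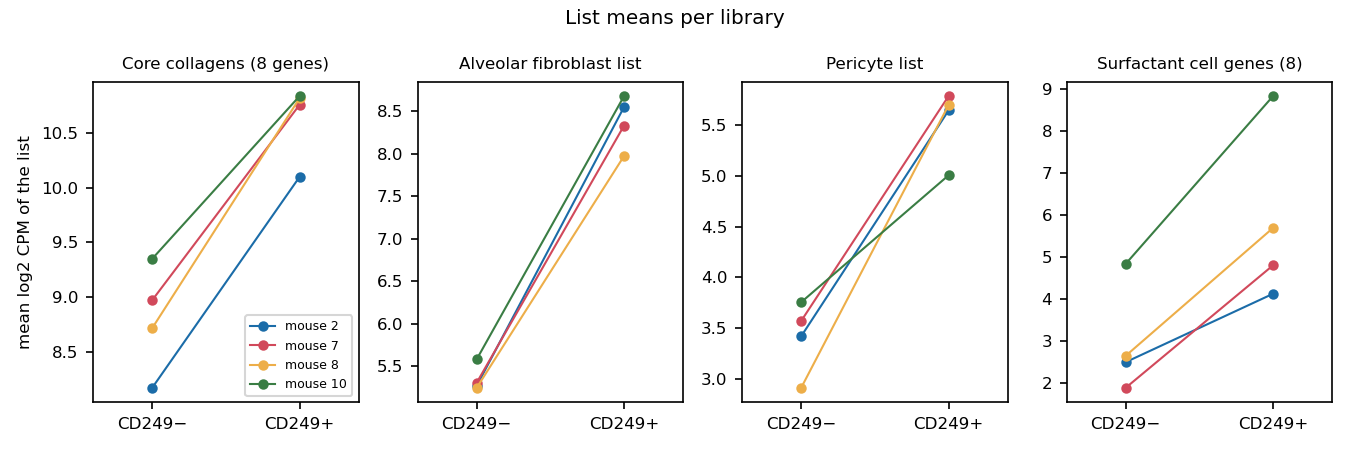
Mean log2 CPM per library of 8 core collagen genes, the alveolar fibroblast list, the pericyte list and 8 surfactant and alveolar epithelial genes, with lines joining the libraries of a mouse. Both 8-gene sets were chosen after the data were seen: the collagen mean was 8.80 in CD249− and 10.6 in CD249+ libraries (exact permutation p = 0.0286) and the epithelial mean 2.98 and 5.87 (exact permutation p = 0.0857).

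**Figure D4:**
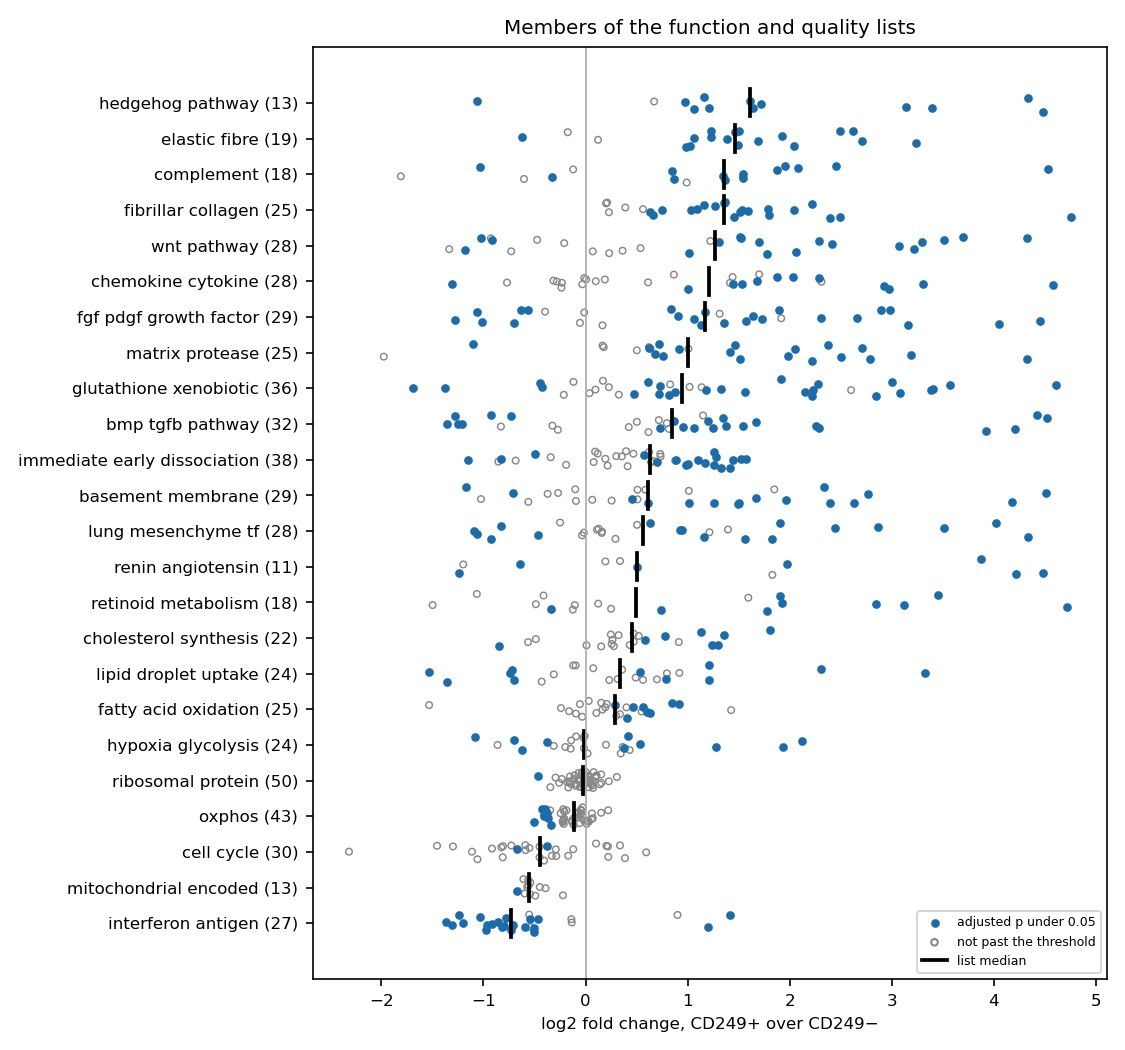
Log2 fold change, CD249+ over CD249−, of each measured member of the 24 function and quality lists (number of members in parentheses), with filled points for adjusted p under 0.05, open points for the rest and a bar at the list median. Medians run from 1.61 for hedgehog genes to -0.73 for interferon and antigen presentation genes, and ribosomal protein genes gather around -0.02.

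Signalling genes rose in several families. Of 13 hedgehog pathway genes 11 rose, 1 fell and 1 did not pass, with the same counts adjusted over the list alone. The median log2 fold change was 1.61 (camera adjusted p = 8.87e-06, and adjusted p = 0.274 with an estimated correlation). The transcription factor genes Foxf2 and Gli2 rose by 4.34 and 3.40 and the transducer gene Smo by 1.06, while Foxf1, which lung endothelium also expresses, fell by 1.06. Of 28 Wnt pathway genes 15 rose, 3 fell and 10 did not pass, with the same counts adjusted over the list alone. The list had a median of 1.27 (camera adjusted p = 0.00103, and adjusted p = 0.274 with an estimated correlation). The receptor gene Lgr5 rose by 4.33, Wnt4 by 3.22, Dkk3 by 2.29 and Fzd1 by 2.06, and Sfrp4, Fzd4 and Nkd1 fell by 1.18, 1.02 and 0.91. Of 29 FGF, PDGF and other growth factor genes 17 rose, 6 fell and 6 did not pass, with the same counts adjusted over the list alone, at a median of 1.17 (camera adjusted p = 0.000419, and adjusted p = 0.274 with an estimated correlation). Fgf10, a growth factor of lung mesenchyme, went from 4.37 ± 1.94 to 73.1 ± 3.42 CPM (SD, n = 4, log2 fold change 4.05), Fgf7 rose by 2.98, Fgf2 by 2.90 and the feedback inhibitor gene Spry1 by 1.73. Of 32 BMP and TGF-beta genes 16 rose, 6 fell and 10 did not pass, 18 rose and 6 fell adjusted over the list alone, and the median was 0.84 (camera adjusted p = 0.00172, and adjusted p = 0.274 with an estimated correlation). Bmp5 rose by 4.52 and Bmp3 by 4.42, and the BMP target gene Id1 fell by 1.25. Of 28 lung mesenchyme transcription factor genes 12 rose, 5 fell and 11 did not pass, 13 rose and 5 fell adjusted over the list alone, and the median was 0.57 (camera adjusted p = 0.00348, and adjusted p = 0.314 with an estimated correlation). Tbx4 had the smallest standard error of the members named (4.02, SE 0.12, adjusted p = 3e-07), from 20.2 ± 2.62 to 328 ± 15.4 CPM (SD, n = 4), and Tcf21 rose by 2.87.

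Among genes of small-molecule metabolism 4 lists were called higher, and the lipid droplet and the hypoxia and glycolysis lists moved both ways. Of 36 glutathione and xenobiotic genes 21 rose, 4 fell and 11 did not pass, 24 rose and 4 fell adjusted over the list alone. Over its members the median was 0.95 (camera adjusted p = 2.64e-06, and adjusted p = 0.365 with an estimated correlation). The glutathione transferase genes Gsta3 and Gstt1 rose by 3.08 and 2.28, the monooxygenase gene Fmo2 by 1.91 and the alcohol dehydrogenase gene Adh1 by 2.84, and Cyp1a1, Fmo1, Gclm and Sod1 fell by 1.69, 1.37, 0.44 and 0.43. Of 18 retinoid genes 8 rose, 1 fell and 9 did not pass, 9 rose and 2 fell adjusted over the list alone. The median log2 fold change was 0.50 (camera adjusted p = 0.0115, and adjusted p = 0.365 with an estimated correlation). Lrat, whose enzyme esterifies retinol for storage, went from 7.92 ± 1.70 to 208 ± 43.2 CPM (SD, n = 4, log2 fold change 4.71), and Aldh1a1 rose by 3.46. Of 22 cholesterol synthesis and uptake genes 7 rose, 1 fell and 14 did not pass, 12 rose and 2 fell adjusted over the list alone, and the median was 0.45 (camera adjusted p = 0.00915, and adjusted p = 0.417 with an estimated correlation). The sterol desaturase gene Sc5d rose by 1.35 and Insig1 by 1.13, and Stard4 fell by 0.85. Of 25 fatty acid oxidation genes 8 rose and 17 did not pass, with the same counts adjusted over the list alone, at a median of 0.29 (camera adjusted p = 0.0118, and adjusted p = 0.342 with an estimated correlation), among them Acaa2 (0.92), Hadh (0.85) and Etfa (0.63). Of 24 lipid droplet and uptake genes 6 rose, 5 fell and 13 did not pass, 7 rose and 5 fell adjusted over the list alone, and the list was not called (median 0.34, camera adjusted p = 0.483). G0s2, an inhibitor of triglyceride lipase, rose by 3.33 and Angptl4 by 2.31, and Hilpda fell by 1.53 and the lipase gene Pnpla2 by 0.74. Of 24 hypoxia and glycolysis genes 6 rose, 4 fell and 14 did not pass, with the same counts adjusted over the list alone, and the list was not called. Its median was -0.01, its mean 0.14 and camera's direction up (adjusted p = 0.687), and the sign of the median changed with RLE scaling.

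In the renin-angiotensin list 5 of 11 measured genes rose, 2 fell and 4 did not pass, with the same counts adjusted over the list alone, and the list was not called (median 0.51, camera adjusted p = 0.228). The neprilysin gene Mme rose from 5.79 ± 3.90 to 85.6 ± 24.3 CPM (SD, n = 4, log2 fold change 3.87), and Agt, which encodes angiotensinogen, rose by 4.48. Agt was near the floor in CD249− cells, at 0.617 ± 0.722 CPM (SD, n = 4). It gave 5.44 without the CD249− library of mouse 10 and 3.84 without both libraries of mouse 8. Ace, the gene of angiotensin-converting enzyme, which lung endothelium expresses strongly, fell from 2043 ± 397 to 867 ± 220 CPM (SD, n = 4, log2 fold change -1.24), and Prcp fell by 0.65. Interferon and antigen presentation genes were lower in CD249+ cells, as were the endothelial and leukocyte lists: 19 of 27 fell, 2 rose and 6 did not pass, with the same counts adjusted over the list alone. The list had a median of -0.73 (camera adjusted p = 9.14e-05, and adjusted p = 0.440 with an estimated correlation). The proteasome gene Psmb9 fell by 1.24, the class I antigen gene H2-D1 by 0.97 and Bst2 from 216 ± 11.9 to 94.2 ± 18.0 CPM (SD, n = 4). Ifi27l2a rose by 1.42 and Ifit2 from 14.9 ± 5.07 to 34.2 ± 5.46 CPM (SD, n = 4). Of 18 complement genes 11 rose, 2 fell and 5 did not pass, 12 rose and 2 fell adjusted over the list alone. Over its members the median was 1.36 (camera adjusted p = 0.00387, and adjusted p = 0.447 with an estimated correlation). C4b rose by 2.45, Cd59a by 2.09 and C1s1 by 1.88, and Clu and Cr1l fell by 1.03 and 0.33. Of 28 chemokine and cytokine genes 11 rose, 1 fell and 16 did not pass, with the same counts adjusted over the list alone, at a median of 1.21 (camera adjusted p = 0.012, and adjusted p = 0.457 with an estimated correlation). Cxcl14 rose by 4.58, Tnfsf13b, the gene of B-cell activating factor, by 2.97, Il34 by 2.93 and Lif by 2.04, and Cx3cl1 fell by 1.31. The list's call was lost without the CD249+ library of mouse 7 (median 0.78, adjusted p = 0.0501) and with members of at least 10 CPM alone (median 0.15, adjusted p = 0.163).

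Of 38 immediate early and dissociation genes, which tissue digestion can induce, 15 rose, 3 fell and 20 did not pass, 18 rose and 3 fell adjusted over the list alone. The median log2 fold change was 0.63 (camera adjusted p = 0.0154, and adjusted p = 0.626 with an estimated correlation). Gadd45b rose by 1.57 and Egr1 by 1.44, while Klf2, a gene of endothelium under flow, fell by 1.15, Klf4 by 0.83 and Dusp6 by 0.50. The call was lost without the CD249− library of mouse 2 or 10 or the CD249+ library of mouse 7 or 8 (adjusted p = 0.0521, 0.0535, 0.0501 and 0.0641). Of 43 oxidative phosphorylation genes 8 fell and 35 did not pass, with the same counts adjusted over the list alone. The list had a median of -0.12 (camera adjusted p = 0.00601, and adjusted p = 0.603 with an estimated correlation), and Ndufa4 fell by 0.50 and Atp5h by 0.41. The Atp5h call was lost without both libraries of mouse 10 (adjusted p = 0.0571). Of 13 genes of the mitochondrial genome mt-Nd3 fell by 0.67 (adjusted p = 0.0363) and 12 did not pass, at a median of -0.56 (camera adjusted p = 0.012, and adjusted p = 0.603 with an estimated correlation). Adjusted over the list alone 0 were called by edgeR, 9 had an unadjusted p under 0.05, and over all genes DESeq2 called 7 and limma-voom 1. The mt-Nd3 call was lost without the CD249− library of mouse 7 or 8 or the CD249+ library of mouse 2, 8 or 10 (adjusted p = 0.0656 to 0.0978) and the list's call without the CD249+ library of mouse 2 (adjusted p = 0.0524). With mouse as a block mt-Nd4l, mt-Nd6 and mt-Atp8 were called as well (adjusted p = 0.0065, 0.00909 and 0.00229). The mitochondrial share of all counts was 1.05% ± 0.348 in CD249− and 0.713% ± 0.128 in CD249+ libraries (SD, n = 4, exact permutation p = 0.114), lower in all 4 mice (paired exact permutation p = 0.125, the smallest that 4 pairs can give). Of 30 cell cycle genes Mcm3 fell by 0.68 and Mcm6 by 0.38 and 28 did not pass, 1 fell adjusted over the list alone, and the median was -0.45 (camera adjusted p = 0.0207, and adjusted p = 0.457 with an estimated correlation). The Mcm3 call was lost without both libraries of mouse 8 (adjusted p = 0.0623). The list's call was lost without the CD249− library of mouse 8 (adjusted p = 0.0823) and with members of at least 10 CPM alone (adjusted p = 0.0812), and that of Mcm6 with mouse as a block (adjusted p = 0.051) and without the CD249− or CD249+ library of mouse 2, 7 or 10 (adjusted p = 0.0635 to 0.0971). Of 50 ribosomal protein genes Rpl27 fell by 0.47 (adjusted p = 0.0473) and 49 did not pass, at a median of -0.02 (camera adjusted p = 0.503). Adjusted over the list alone edgeR called 0 of them, 2 had an unadjusted p under 0.05, and over all genes DESeq2 and limma-voom called 1 each. The Rpl27 call was lost with mouse as a block (adjusted p = 0.0702) and without any single library (adjusted p = 0.0603 to 0.119), while the block called Rps2, Rpl38 and Rps15 (adjusted p = 0.0115, 0.0454 and 0.0429).

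Of the 36 lists 27 passed camera's threshold, 20 higher and 7 lower in CD249+ cells. The test fry, which tests whether the members of a list move on balance one way without comparing them with other genes, called 22 of the 36.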

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

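The counts of splits were planned before the data were examined, and every other test below was chosen only after the result was seen.

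The 35 ways to part the 8 libraries into 4 and 4 were each fitted in the same way. The real grouping called 4468 genes, the highest other split 2, and 1 of 35 splits, the real one, gave as many. That share takes the libraries as exchangeable, while they are paired by mouse, so by itself it does not exclude chance for the count of genes. The split with 2 calls parts mice 2 and 8 from mice 7 and 10, which differ in sex-linked transcripts. Xist stood at 93.9, 2.10, 113 and 0.210 CPM in CD249− cells of mice 2, 7, 8 and 10. Only 8 of the 35 splits part every same-mouse pair, too few for a share under 0.05, and among them the highest other count was 0 (edgeR). The others keep both libraries of at least 2 mice together, and the split of mice 7 and 8 from mice 2 and 10 also called 0. For gene lists camera called 27 under the real grouping and 28 under another split, so 2 of 35 splits gave as many and chance is not excluded for the count of lists. That other split joins the CD249− libraries of mice 2, 7 and 8 with the CD249+ library of mouse 2, so it keeps most of the real contrast. Among the splits that part every pair the highest other count was 26. The split by haemoglobin level gave 13, and that of mice 2 and 8 from mice 7 and 10 gave 12.

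Endothelial genes were lower in CD249+ cells although both fractions were gated as CD31 negative. All of the 23 endothelial list members with a mean of at least 10 CPM were lower in all 4 mice (100%), and none of the 24 genes is in another list, though how many of them lung fibroblasts also express was not analysed here. Plvap, the most abundant, stood at 3606 and 1272 CPM. Library scaling is argued against, because the endothelial mean relative to the ribosomal protein mean differed by -1.445 log2 CPM (2.316 ± 0.3 and 0.8708 ± 0.425, SD, n = 4, exact permutation p = 0.0286, the smallest that 4 against 4 can give). More endothelial cells among the CD249− cells stay open as a candidate explanation, as does a difference in expression between the sorted fibroblasts themselves, which was not tested.

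Alveolar fibroblast genes, of which 14 of the 24 written are also in other lists, were higher in CD249+ cells. A higher share of fibroblasts of every kind is argued against as the whole explanation: the alveolar mean relative to the core collagen mean rose by 1.205 log2 CPM (-3.451 ± 0.388 and -2.247 ± 0.546, SD, n = 4, exact permutation p = 0.0286). RNA of alveolar epithelial cells is argued against as the whole explanation: with the mean of 8 surfactant and epithelial genes as a covariate the alveolar mean still rose by 2.83 log2 CPM (95% lower bound 2.24, and 1.97 at the lowest without 1 library), against 3.03 without it. The spans over the CD249+ libraries, 0.705 log2 units for the alveolar mean and 4.56 for Sftpc, do not decide it, since they were 0.576 and 1.29 without mouse 10. The difference between the sorted fractions that the design names stays open as an untested explanation.

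Pericyte genes, of which 5 of the 22 written are also in other lists, were also higher in CD249+ cells. Whether a higher share of fibroblasts of every kind explains this is not decided. The pericyte mean rose by 1.659 log2 CPM relative to the adventitial mean (-4.379 ± 0.36 and -2.721 ± 0.471, SD, n = 4, exact permutation p = 0.0286). The adventitial mean itself differed by -1.369 log2 CPM relative to the core collagens, so the choice of reference sets much of that rise. Relative to the core collagens the pericyte mean rose by 0.2896 log2 CPM (-5.387 ± 0.455 and -5.097 ± 0.568, SD, n = 4, exact permutation p = 0.429), so cells that carry both collagen and pericyte genes stay open. The fibrillar collagen list, written beforehand, went from 6.896 to 8.285 log2 CPM and the pericyte list from 3.415 to 5.532, a contrast that was not tested. Of the 17 pericyte members that rose, 13 had their lowest CD249+ level in mouse 10, where 0 of 20 alveolar members that rose had theirs, and 19 of those were lowest in mouse 8. Pericytes among the CD249+ cells, apart from alveolar fibroblasts, therefore stay open as a candidate explanation, since the gate did not exclude them.

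Of 368 groups of 4 libraries examined, 34 had 1 library far from the other 3. In these the gap to the nearest passed Dixon's critical value at 95%. Chance gives that in about 1 in 20 groups of independent, normally distributed values. Gene values were taken as CPM without a log, and genes and lists vary together, so that rate need not hold here. The gap as a share of the range is given for each. Surfactant genes were far higher in mouse 10: Sftpb 0.938 in CD249+ (478.6 against 45.22 CPM) and 0.911 in CD249− cells, Sftpa1 0.919 (1889 against 230.8 CPM) and Sftpc 0.936 (7551 against 781.1 CPM) in CD249+ cells, and the epithelial list 0.896 in CD249− cells. In CD249− cells mouse 10 was also highest for Bpifa1 (0.89, 46.15 against 5.84 CPM), Prkg2 (0.841, 6.147 against 1.996 CPM), Adamts15 (0.96), Bmp5 (0.843), Fgf10 (0.863), Adh7 (0.887) and the ductal myofibroblast list (0.96). In CD249+ cells it was highest for Insig1 (0.859), Fgf10 (0.852) and Cxcl14 (0.875, 405.5 against 248.1 CPM) and lowest for Id1 (0.863). Mouse 7 was highest in CD249− cells for the platelet genes Gp5 (0.909, 78.63 against 18.35 CPM), Ppbp (0.871, 202.6 against 55.98 CPM) and Gp9 (0.857, 26.3 against 7.383 CPM) and for Cox5a (0.889), and in CD249+ cells for Rps15 (0.985). Mouse 2 was highest for Cdh5 in both fractions (0.842 in CD249− and 0.924 in CD249+) and for Dpp4 (0.897) and Ace (0.856) in CD249+ cells. It was lowest for Adamtsl2 (0.87), Angptl4 (0.854) and the chondrocyte list (0.874) in CD249− cells and for Ltbp2 (0.888), Lif (0.877) and the elastic fibre list (0.845) in CD249+ cells. Mouse 8 was lowest for Adrb3 in CD249− cells (0.993, 0 against 1.191 CPM) and for Mmp11 in CD249+ cells (0.836), and highest for the leukocyte list in CD249+ cells (0.905).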

How the results depend on the processing

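The fits on mice 7 and 8 alone and on mice 2 and 10 alone were chosen after seeing the data, and the other alternatives were planned. Enpep kept its direction and call under all 25 alternatives tried for it (log2 fold change 4.52 to 5.27, highest adjusted p = 0.0176). Of 134 named genes called, 75 kept their call and direction under every alternative, and no named gene or list past the threshold changed direction under any alternative tried for it.

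With mouse as a block edgeR called 5298 genes (2809 higher, 2489 lower), 4335 of them among the 4468 called without it, and camera called 28 lists. Of the named genes called, 132 kept the call and 2 lost it, Mcm6 (adjusted p = 0.051) and Rpl27 (0.0702). Ptprc, mt-Nd4l, mt-Nd6, mt-Atp8, Rps2, Rpl38 and Rps15 gained it, as did the adventitial list (median 0.38, adjusted p = 0.037), and the block changed no other named call. Enpep gave 4.86 (adjusted p = 7.57e-07). DESeq2 called 5210 genes, and 6045 with the block.

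With library size only, 43.9% of calls were higher, against 54.9% with TMM. At an adjusted p under 0.01 there were 2717 calls (1598 higher, 1119 lower), and against a log2 fold change of 0.5 there were 2118 (1389 higher, 729 lower; 65.6% higher), fewer by construction. Mice 7 and 8 alone gave 1251 lower genes, and mice 2 and 10 alone 668 calls (570 higher, 98 lower; 85.3% higher), with fewer libraries. Leaving out 1 library or mouse gave 2978 to 4458 calls, 1777 to 2479 higher and 1201 to 1979 lower.

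With an estimated correlation camera called 0 of 36 lists (lowest adjusted p = 0.274, 5 at an unadjusted p under 0.05), and 0 with the block as well (lowest 0.342). Fry called 22. It lost the leukocyte (adjusted p = 0.0728), cell cycle (0.0728), red cell and platelet (0.157), mitochondrial genome (0.157), immediate early (0.147) and oxidative phosphorylation (0.0542) lists and gained the renin-angiotensin list (0.0229). With members of at least 10 CPM alone camera called 24, without the chemokine (0.163), cell cycle (0.0812) and red cell and platelet (0.0541) lists. Without a low-count filter the mesothelial list was gained (0.0241). Mice 7 and 8 alone gained the adventitial (0.000287), mesothelial (0.0329) and renin-angiotensin (0.0373) lists and lost oxidative phosphorylation (0.0933), and mice 2 and 10 alone gained the mesothelial list (0.0229) and lost basement membrane (0.0613), cell cycle (0.0683), chemokine (0.131) and retinoid (0.151) lists. Of 27 lists called, 19 were kept under every alternative with the preset correlation. The cause of these changes was not tested. Depth limits genes near the floor most. In simulated counts 66% of genes changed 2-fold were called, but these had a CD249− mean of at least 1 CPM, so the share does not describe genes near the floor.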

Other observations

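The test of adventitial genes against collagens was chosen only after the result was seen and takes the libraries as unpaired.

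Adventitial fibroblast genes fell relative to the core collagens, by -1.369 log2 CPM (-1.007 ± 0.177 in CD249− and -2.376 ± 0.272 in CD249+ libraries, SD, n = 4, exact permutation p = 0.0286). A higher share of fibroblasts of every kind would raise both alike, so the makeup of the fibroblasts may differ between the fractions, with fewer adventitial cells for the same collagen in CD249+ cells as a candidate explanation. Endothelial genes fell as well (median -1.46, 22 of 24 lower), and the adventitial members that fell, Ly6c1 (-1.52), Ly6a (-1.49), Dpp4 (-1.16) and Sema3c (-1.10), moved by about as much, so fewer cells of another kind that express them stay open too. The 8 core collagens were all higher in CD249+ cells, by 1.83 on average (exact permutation p = 0.0286). Of the 28 genes written in the adventitial list 13 are also in other lists.

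Haemoglobin transcripts summed to 26.8, 497, 502 and 15.7 CPM in CD249− cells of mice 2, 7, 8 and 10 and to 15.6, 129, 366 and 12.1 CPM in CD249+ cells, lower in CD249+ cells of all 4 mice. Their mean did not differ past the threshold between the fractions (exact permutation p = 0.514) or within mice (paired exact permutation p = 0.125, the smallest that 4 pairs can give). The labels give no batch that follows this difference between mice.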
